A study of Homo sapiens with 4 samples.

How the data were processed

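Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in MCF-7 cells, an established estrogen receptor-positive human breast cancer line. ChIP-seq isolates the DNA fragments bound by a protein with an antibody and sequences them, so that bound sites appear as peaks of reads along the genome. The series holds 4 libraries, 1 per condition. They are GATA3 ChIP with estradiol, GATA3 ChIP with vehicle, p300 ChIP with estradiol and p300 ChIP with vehicle. Per the labels' protocols, cells were kept in hormone-depleted medium for 72 h and then exposed for 45 min to 10 nM estradiol (E2) or to DMSO as vehicle. The peak lists of the 2 GATA3 libraries were used. The 2 p300 libraries were not analysed here.

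Each GATA3 file is a list of peaks of 1 library, with a chromosome, a start, an end and a score per peak. Peaks were called with MACS against a control, per the file headers. Each header names a single library, so peaks were taken as called per library and not on pooled samples. The genome build was hg18, per the submitters' processing notes. In both lists the last peak on chromosome 3 ended beyond the last GRCh38 gene, at 199329607 for E2 and 199193086 for vehicle, so the coordinates were not those of GRCh38. The aligner, the MACS version and settings, the read filters and the nature of the control are not given in the sources used here. The score that the authors deposited for each peak has no unit stated in the file. The lowest score was 50 in both lists, and no cut-off is stated. Scores were used to rank, describe or filter peaks within 1 list. Where scores of both lists stand side by side, as medians, as a rank or log correlation over matched peaks or under a common cut-off of 100, they describe each list and measure no change between conditions. Neither the number of reads per library nor the number per peak is in the lists used here, so the depth is unknown. Peak calling finds more and wider peaks in a deeper or better enriched library, which bears on every difference between the lists.

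Peaks were compared as they were listed, including 53 E2 and 24 vehicle peaks outside chromosomes 1 to 22 and X. A peak was called shared when it overlapped a peak of the other list by at least 1 bp, and E2-only or vehicle-only otherwise. "E2-only" therefore means that the vehicle list held no overlapping peak at the authors' threshold, not that GATA3 was absent. Shares are given with Wilson 95% intervals, which cover counting error over peaks only. With 1 library per condition there is no replicate error, peaks are not replicates, and no p-value was computed. Chance overlap was measured by rotating the vehicle list along each chromosome by a random amount, 1000 times, within the span of the peaks of both lists. Rotation also puts peaks into unsequenced gaps, so it gives a slightly low chance overlap and a slightly long chance distance. Distances between matched peaks and from E2-only peaks to vehicle peaks ran from centre to centre, since the lists give no summits. Gaps given for named peaks ran from edge to edge. Rotated E2-only peaks that fell on a vehicle peak were left out of the chance distance. The median score of shared peaks was set beside the medians of 10000 random sets of the same size from the same list. Intervals of medians and of their ratios came from 1000 bootstrap samples of peaks. Windows of 100 kb were counted on a fixed grid by peak centre. Coordinates are 1-based hg18 positions.

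The peaks named in the text follow a rule written before the data were examined, as were the alternatives unless stated otherwise. The rule took the 10 highest-scoring shared peaks of the E2 list, the 10 highest E2-only peaks and the 5 highest vehicle-only peaks. It also took the 5 windows of 100 kb with the most peaks in each list and the 5 with the largest excess of E2 peaks, with ties. Windows without vehicle peaks and peaks of 3 kb or more were chosen after their values were seen. Planned results on distance to start sites, on fixed gene lists and on DNA motifs need the sequence or the gene positions of hg18. They were not run, because the reference table used here is of GRCh38 and coordinates were not converted. For the same reason no peak is assigned to a gene.

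The overlap code was tested on simulated data. A list with 5000 planted overlapping peaks gave back 5000. On the real lists, bedtools 2.31.1 counted the same 18208 E2 and 18405 vehicle peaks as overlapping. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures used matplotlib 3.10.9. Alternatives covered the overlap that counts as shared, stricter score thresholds, merging of neighbouring peaks, lists of equal length and leaving out chromosomes 1, 17 and 20.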

Results

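The series addressed how GATA3, together with the estrogen receptor ERalpha and FOXA1, occupies the genome of MCF-7 cells with and without estrogen. GATA3 is a zinc-finger transcription factor of luminal breast epithelium, and FOXA1 is a forkhead factor that opens chromatin. GATA3 binding was measured by ChIP-seq after 45 min with 10 nM estradiol (E2) or with vehicle, in 1 library per condition. The E2 list held 38575 GATA3 peaks and the vehicle list 20728. The sequencing depth of the libraries is unknown, and there were no replicates, so the intervals given cover counting error over peaks only.

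GATA3 peaks were more numerous and wider with estradiol. The E2 list was 1.86 times as long as the vehicle list and covered 18.7 Mb, against 8.22 Mb with vehicle. The median peak was 434 bp wide with E2 (interquartile range 347 to 539 bp) and 349 bp wide with vehicle (281 to 430 bp). Of 17850 peak pairs that matched one to one, 15693 (87.9%) were wider with E2, with median widths of 491 bp with E2 and 361 bp with vehicle. The authors' peak score, which is not compared between the lists, had a median of 119 in the E2 list (interquartile range 71.5 to 272) and of 101 in the vehicle list (66.8 to 191). Scores piled up at 1 value in the E2 list, where 177 peaks scored 3100 or more, 151 of these exactly 3100 and 26 above it. In the vehicle list, 3 peaks scored exactly 3100 and 2 scored above it. What a score of 3100 stands for is not stated, so the order among the highest E2 peaks carries little information.

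Most GATA3 sites listed without hormone were also listed with estradiol. Of the vehicle peaks, 18405 (88.8%, Wilson 95% interval 88.4 to 89.2%) overlapped an E2 peak, and 2323 were vehicle-only. Of the E2 peaks, 18208 (47.2%, 46.7 to 47.7%) overlapped a vehicle peak, and 20367 were E2-only. When the vehicle list was rotated along the chromosomes, a median of 1.18% of its peaks overlapped an E2 peak (range 0.946 to 1.49% over 1000 rotations), so the observed overlap was 75.1 times that of unrelated positions. The matched peaks sat at nearly the same place, with a median distance of 38 bp between centres, and 87.4% of pairs lay within 100 bp. Over the one-to-one pairs, the scores of the lists had a Spearman rho of 0.75 and, on a log scale, a Pearson r of 0.79; these are correlations across peaks of a single pair of libraries, and peaks are not independent replicates. When each list was limited to its 20728 highest peaks, 70.8% of the E2 peaks (70.2 to 71.4%) and 71.9% of the vehicle peaks (71.3 to 72.5%) were shared.

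Shared peaks had higher median scores than unshared peaks in both lists. Within the E2 list, shared peaks had a median score of 243 and E2-only peaks 79.5, a ratio of 3.06 (bootstrap interval 3.00 to 3.11). Within the vehicle list, the medians were 113 for shared and 59.3 for vehicle-only peaks, a ratio of 1.90 (1.87 to 1.93). In both lists the shared median was above all 10000 random sets of the same size, the highest of which reached 123 in the E2 list and 102 in the vehicle list. In the highest-scoring decile of the E2 list, 90.5% of peaks were shared (89.5 to 91.4%), and in the lowest decile 9.80% (8.90 to 10.8%).

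Unmatched peaks were found at the top of the E2 list and not at the top of the vehicle list. Each of the 1000 highest vehicle peaks overlapped an E2 peak, and for a count of 0 of 1000 the Wilson upper limit of the vehicle-only share is 0.383%. Among the 1000 highest E2 peaks, 60 (6%, 4.69 to 7.65%) had no overlapping vehicle peak. Among the 2000 highest of each list, 146 E2 peaks (7.3%, 6.24 to 8.52%) and 0 vehicle peaks were without a partner. The longer E2 list offers more partners, but 0 of the 1000 and 0 of the 2000 highest vehicle peaks were unmatched also when the partners were limited to the 20728 highest E2 peaks, a setting chosen after seeing the data. In the lowest-scoring decile of the vehicle list, 61.2% of peaks (59.1 to 63.2%) were still shared.

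**Figure D1:**
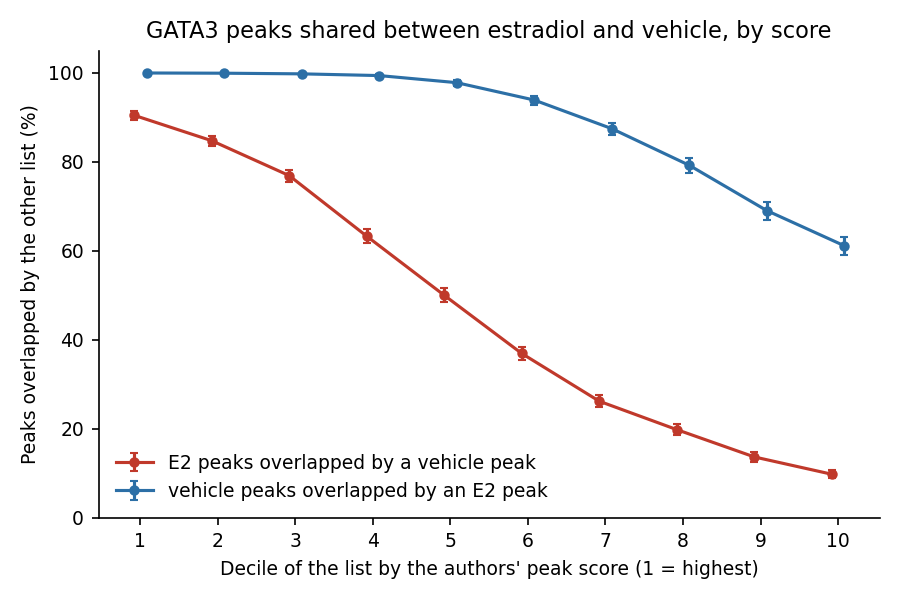
Percent of GATA3 peaks overlapped by at least 1 bp by a peak of the other list (vertical axis), in deciles of each list from the highest to the lowest score (horizontal axis). Points are the E2 list (red) and the vehicle list (blue), bars are Wilson 95% intervals over peaks. The share goes from 90.5% to 9.80% in the E2 list and from 100% to 61.2% in the vehicle list.

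The highest E2-only site lay on chromosome 12 at 50828641 to 50829591 and scored 3228, among the peaks at or above 3100. The next was on chromosome 21 at 45574316 to 45575119, with a score of 3202. Sites on chromosome 11 at 72616266 to 72617289 and on chromosome 14 at 68106304 to 68107105 both scored 3100. They were followed by sites on chromosome 9 at 96584866 to 96585730 (score 3009), on chromosome 11 at 2170831 to 2171634 (2955) and on chromosome 14 at 64654417 to 64655341 (2756). The remaining 3 of the 10 highest were on chromosome 8 at 67587468 to 67588204 (2714), on chromosome 7 at 156777894 to 156778619 (2631) and on chromosome 10 at 29254134 to 29254949 (2581). The gap between edges to the nearest vehicle peak was 1.85 kb from the chromosome 11 site at 2170831, 3.99 kb from the chromosome 8 site and 4.38 kb from the chromosome 14 site at 68106304. It was 32.3 kb from the chromosome 12 site, 67.0 kb from the chromosome 21 site and 89.0 kb from the chromosome 14 site at 64654417.

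The 10 highest shared sites of the E2 list lay between the 53.8th and the 99.7th percentile of the vehicle scores among the one-to-one pairs. The highest of them, on chromosome 2 at 11597009 to 11597797, scored 3225 in the E2 list, and its vehicle peak scored 314, at the 85.3rd percentile of the vehicle scores among the one-to-one pairs. The sites on chromosome 20 at 57996334 to 57997546 and at 58071022 to 58072109 scored 3224 and 3220 with E2, and their vehicle peaks lay at the 62.9th and 86.5th percentiles. The site on chromosome 13 at 97743225 to 97743867 (E2 score 3212) lay at the 53.8th percentile of the vehicle scores. In contrast, the site on chromosome 3 at 4703699 to 4704468 (E2 score 3215) lay at the 99.7th percentile of the vehicle scores, and the site on chromosome 6 at 138945049 to 138946049 (E2 score 3210) at the 97.7th. The other 4 of the 10, on chromosomes 17, 20, 10 and 11, lay between the 81.7th and the 95.6th percentile. All 10 were above the 99.9th percentile in the E2 list by the way they were chosen. Lower percentiles in the vehicle list follow in part from that choice.

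The highest-scoring vehicle-only sites were on chromosomes 20 and 17. None of the vehicle-only peaks was in the top-scoring decile of the vehicle list and 1 was in the next. The first was on chromosome 20 at 51849525 to 51851694, with a score of 233. The others were on chromosome 20 at 55258806 to 55262495 (223), on chromosome 17 at 54272816 to 54273833 (174), and on chromosome 20 at 45562308 to 45566743 (169) and at 51986601 to 51994427 (168). These 5 peaks were between 1018 and 7827 bp wide, against a median width of 273 bp for vehicle-only peaks. For 3 of the 5, the gap between edges to the nearest E2 peak was under 4 kb. Chromosomes 20 and 17 also held 35 and 24 of the 67 vehicle peaks that were 3 kb wide or more, and 52 and 23 of the 97 such E2 peaks.

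E2-only sites lay closer to sites listed without hormone than rotated positions did. Their median distance to the nearest vehicle peak was 27.0 kb (bootstrap interval 26.1 to 27.8 kb, 20362 peaks on sequences with a vehicle peak). Rotated E2-only peaks had a median distance of 74.3 kb (range 65.5 to 83.0 kb over 1000 rotations). Within 10 kb of a vehicle peak lay 28.0% of E2-only peaks (27.4 to 28.6%), against 11.5% after rotation (10.6 to 12.5%). Rotation does not hold peaks to regions rich in peaks. It therefore cannot tell nearness to these sites in particular from clustering of both classes in the same regions.

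Windows of 100 kb held different numbers of peaks in the E2 and vehicle lists. The windows named here were picked by these counts, so their extreme values follow from the choice. The spread that the ratio of the list lengths alone would give was not measured. Of 16646 windows of 100 kb with a peak in either list, 11213 held more E2 than vehicle peaks, 4409 held equal numbers and 1024 held fewer. The fullest E2 window was on chromosome 8 from 102500001 to 102600000, with 19 E2 and 8 vehicle peaks, where the ratio of the list lengths gives 10.2 vehicle peaks for 19 E2 peaks. It was followed by windows on chromosome 21 from 40600001 to 40700000 (18 E2, 10 vehicle) and on chromosome 9 from 129800001 to 129900000 (18 E2, 6 vehicle). Another 7 windows held 16 E2 peaks each. The largest excess, 12 peaks, was found in the chromosome 9 window, on chromosome 10 from 5500001 to 5600000 (15 E2, 3 vehicle) and on chromosome 20 from 45000001 to 45100000 (16 E2, 4 vehicle). The windows on chromosome 8 (excess 11), on chromosome 16 from 67300001 to 67400000 (16 E2, 6 vehicle) and on chromosome 19 from 13800001 to 13900000 (13 E2, 3 vehicle) came next. The fullest vehicle window, on chromosome 17 from 55200001 to 55300000, held 14 vehicle and 13 E2 peaks. The windows on chromosome 1 from 216700001 to 216800000 (16 E2, 12 vehicle) and on chromosome 10 from 29400001 to 29500000 (14 E2, 12 vehicle) followed. The chromosome 17 window lies in a 1 Mb window with 10 E2 and 6 vehicle peaks of 3 kb or more. Its E2 peak at 55275099 to 55280448 overlapped the vehicle peaks at 55274736 to 55276045 and at 55276090 to 55279309. A wide peak counts once even where it spans several peaks, so the near-equal counts there do not show fewer added sites.

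**Figure D2:**
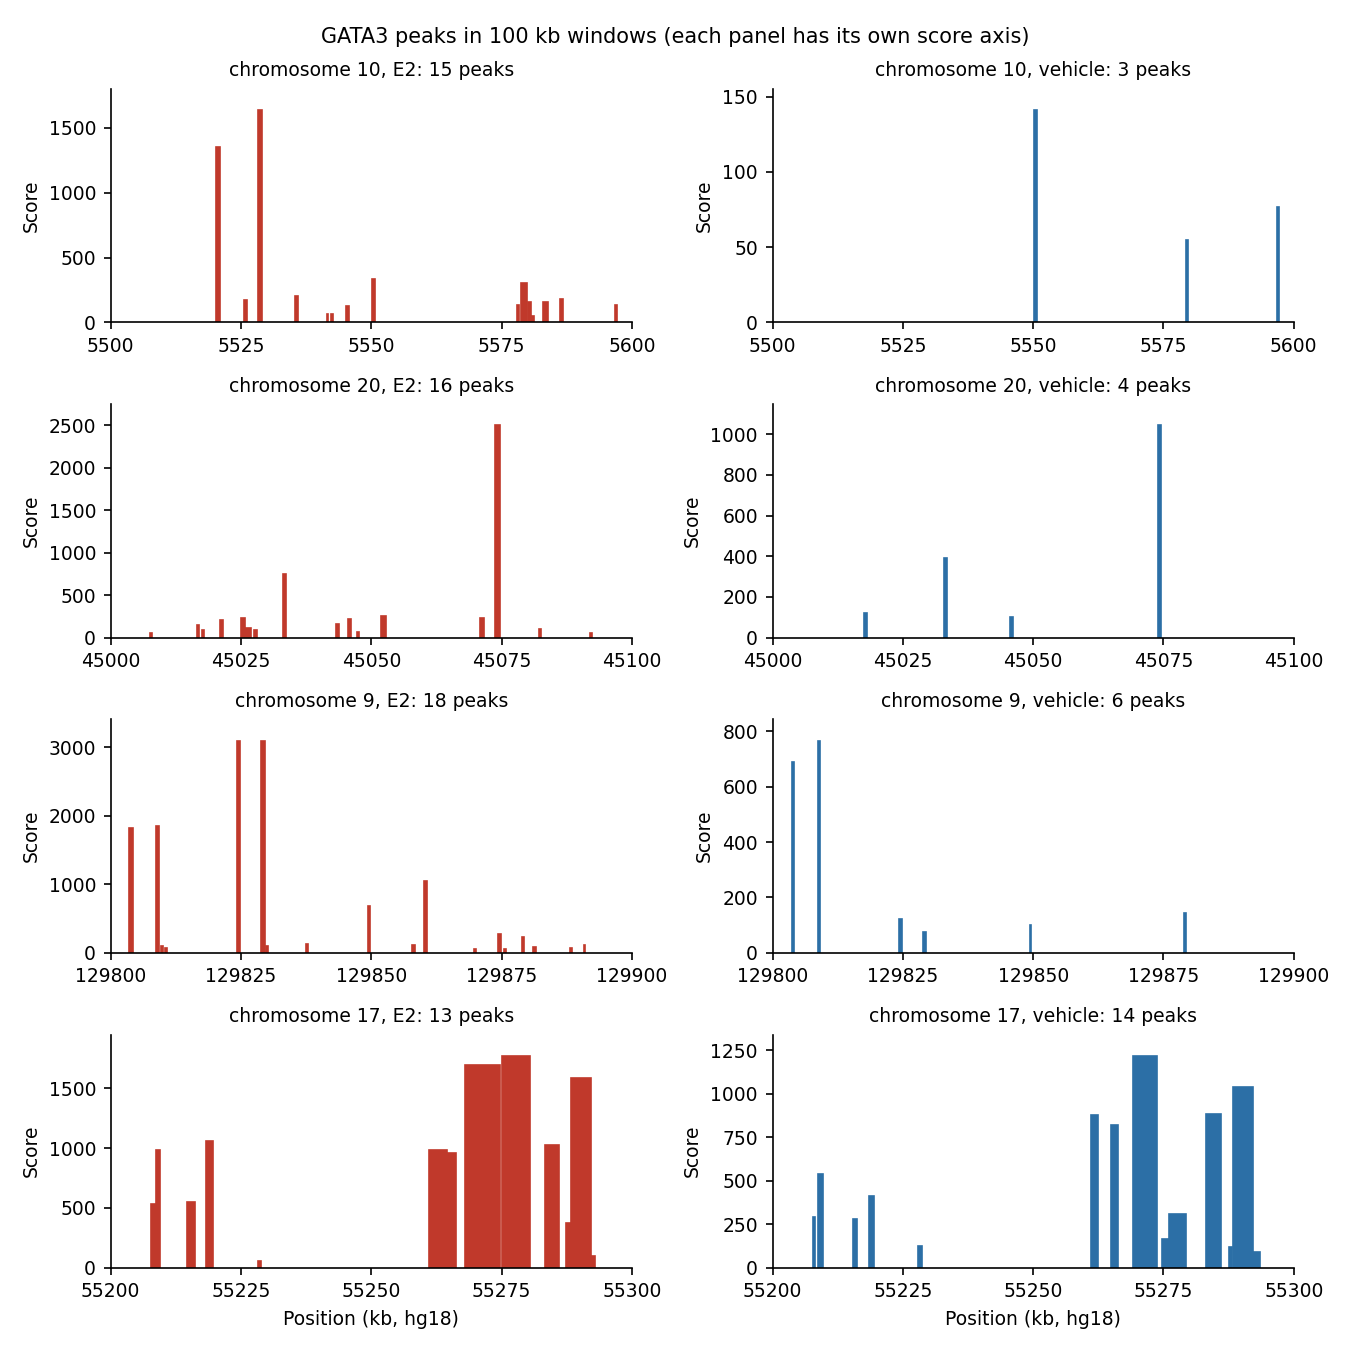
GATA3 peaks in 4 windows of 100 kb, with position in kb (hg18) on the horizontal axis and the authors' score on the vertical axis, for the E2 list (red, left) and the vehicle list (blue, right). Each bar spans a peak from start to end; score axes differ between panels, since scores are not compared between lists. The windows on chromosomes 10, 20 and 9 hold 15, 16 and 18 E2 peaks against 3, 4 and 6 vehicle peaks, and the window on chromosome 17 holds 13 against 14. Windows on chromosomes 10, 20 and 9 were picked for the largest E2 excess, and that on chromosome 17 for the most vehicle peaks. In the chromosome 17 window, the E2 peak at 55275099 to 55280448 counts once but overlaps the vehicle peaks starting at 55274736 and at 55276090.

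All of chromosomes 1 to 22 and X had more peaks with E2 than with vehicle. The ratio of E2 to vehicle peaks was lowest on chromosome 12 (1875 against 1083 peaks, 1.73 times) and chromosome 3 (3146 against 1797, 1.75 times). It was highest on chromosome 19 (824 against 360, 2.29 times), chromosome 22 (479 against 218, 2.20 times) and chromosome 16 (1138 against 537, 2.12 times). Chromosome 12 had the largest share of E2 peaks that were shared, 50.5% (48.2 to 52.7%), and chromosome 19 the smallest, 39.3% (36.0 to 42.7%). The extremes depended on the score threshold, since in the upper 50% of each list chromosome 20 was highest (56.0%), with chromosome 12 at 51.2%, and chromosome 22 was lowest (41.1%), with chromosome 19 at 43.1%. The share of vehicle peaks overlapped by an E2 peak lay between 85.0% on chromosome 7 and 91.9% on chromosome 21. The spread between chromosomes in the E2 list, 11.1 percentage points, was within the range given by rotating the shared calls along the genome (median 9.64 points, and 235 of 1000 rotations as large). Rotation keeps stretches with few shared peaks as whole blocks, so it cannot show whether those stretches arose by chance.

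**Figure D3:**
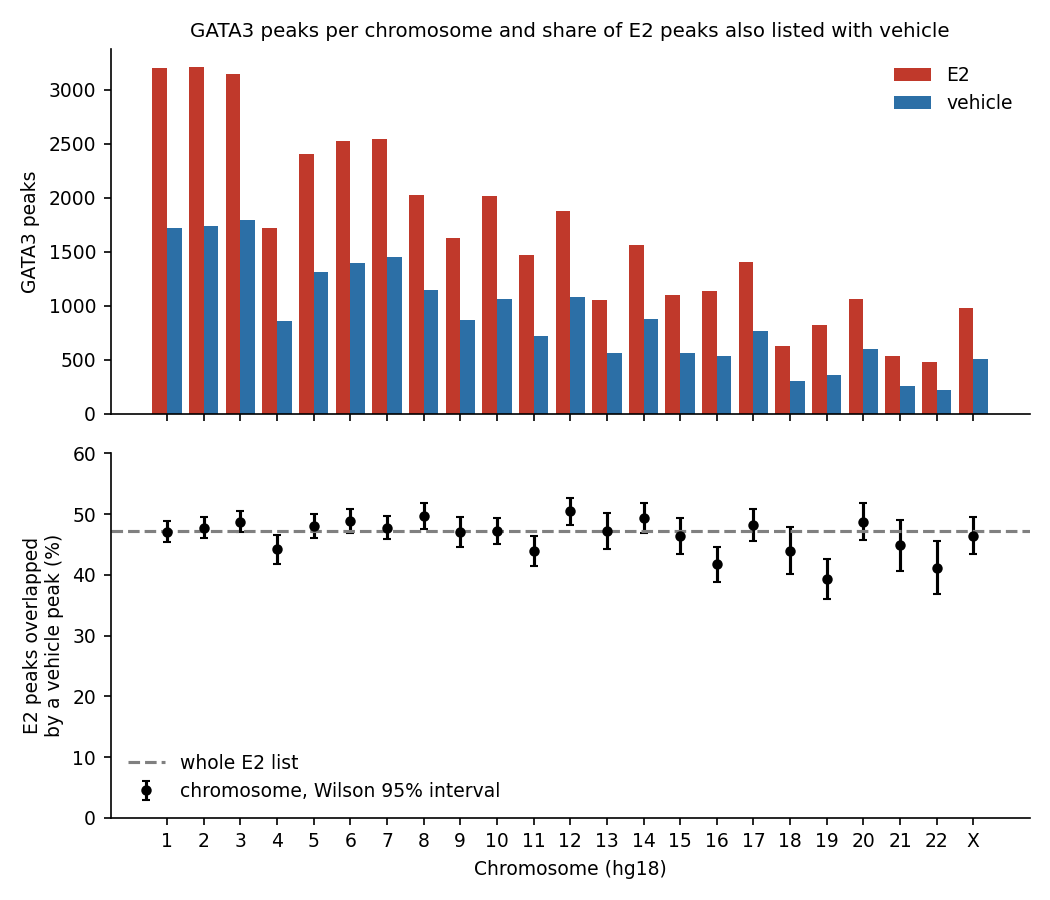
GATA3 peaks per chromosome in the E2 (red) and vehicle (blue) lists (upper panel), and percent of E2 peaks overlapped by a vehicle peak with Wilson 95% intervals (lower panel), for chromosomes 1 to 22 and X in hg18. The dashed line is the whole E2 list, 47.2%; chromosome 12 lies highest at 50.5% and chromosome 19 lowest at 39.3%.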

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

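Of 34 alternatives over 9 results, 18 left the value within its interval (or, for the count ratio, within 1.5 times) and 16 moved it. The ratio of E2 to vehicle peaks stayed between 1.83 and 2.13, the latter with scores of at least 100 in both lists. The share of vehicle peaks overlapped by E2 peaks moved to 85.3% with centres within 200 bp, 89.6% with edges within 1 kb, 94.0% in the upper 50% of each list by score, 69.1% with the upper 50% of the E2 list only and 99.4% with the upper 50% of the vehicle list only. The share of E2 peaks overlapped by vehicle peaks moved to 45.8%, 50.4%, 50.2%, 73.1% and 26.6% under the same settings, and to 48.1% with peaks within 500 bp merged. With the upper 50% of the E2 list only, the E2 share exceeded the vehicle share, so the order of the shares turned, and the E2 share passed 50% with edges within 1 kb and in the upper 50% of each list. Of the one-sided settings, the falls to 69.1% and 26.6% came with fewer partners in the shortened list, and the rises to 73.1% and 99.4% with keeping only its higher-scoring peaks. The overlap of equal-length lists moved to 68.6% with centres within 200 bp. The score ratio of shared to E2-only peaks was 2.86 with edges within 1 kb, and with width in place of the score the ratios were 1.28 in the E2 list and 1.33 in the vehicle list. The width ratios were set against the intervals of the score ratios, a different measure, so counting them as moved carries no information. The median distance of E2-only peaks was 23.0 kb for those in the upper 50% of the E2 list, an alternative chosen after seeing the data, like the settings without peaks of 3 kb or more and without unplaced, haplotype and Y sequences and with partners limited to the N highest E2 peaks, which moved nothing. The range of the shared share over chromosomes went from 11.1 to 14.9 points in the upper 50% of each list, within its sampling interval, while the chromosomes at its ends changed. The cause was not tested for the other moves. Of 11 planned results, 3 (start sites, gene lists, motifs) were not run with their alternatives, because no hg18 sequence or annotation was used. Leaving out replicates was not possible with 1 library per condition. Unknown depth limits what can be said of sites in 1 list only.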

Other observations

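Some regions held clusters of GATA3 peaks in the E2 list with no vehicle peak at all. Of the 100 kb windows, 4876 had E2 peaks and no vehicle peak, and 527 the reverse. In 53 windows there were 5 or more E2 peaks and no vehicle peak. The fullest of these was on chromosome 16 from 83900001 to 84000000, with 9 E2 peaks. It was followed by chromosome 10 from 5700001 to 5800000, with 8 E2 peaks, which lies 100 kb beyond the window on the same chromosome with 15 E2 and 3 vehicle peaks. Windows on chromosome 14 from 98400001 to 98500000, chromosome 19 from 2400001 to 2500000, chromosome 7 from 115900001 to 116000000 and chromosome 7 from 139600001 to 139700000 held 7 E2 peaks each. In the top-scoring decile of the E2 list, 20.6% of the 282 peaks on chromosomes 16, 19 and 22 were E2-only (16.3 to 25.7%), against 8.64% of 3576 peaks elsewhere (7.76 to 9.61%); these chromosomes were picked after their values were seen.

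Very wide GATA3 peaks gathered in a few blocks, most of them the same in both libraries. Peaks of 3 kb or more numbered 97 with E2, of which 52 were on chromosome 20, 23 on chromosome 17 and 12 on chromosome 3, and 67 with vehicle, of which 35, 24 and 8 were on these chromosomes. Chromosome 1 differed, with 7 broad E2 peaks, 4 of them in the 1 Mb window from 114000001 to 115000000, and no broad vehicle peak. Of these 7, however, 5 overlapped a vehicle peak narrower than 3 kb, so most of these sites were also listed with vehicle. The widest peak of either list was on chromosome 17 at 57154163 to 57175828, 21.7 kb wide with E2. The widest with vehicle was on chromosome 20 at 45409012 to 45424084, 15.1 kb wide. The fullest 1 Mb window, on chromosome 20 from 51000001 to 52000000, held 13 broad E2 and 11 broad vehicle peaks. The 10 fullest 1 Mb windows together held 295 E2 and 255 vehicle peaks of any width, a ratio of 1.16, against 1.87 elsewhere. These windows were picked for their broad E2 peaks. A broad peak counts once even where it spans several vehicle peaks, so the lower ratio does not show fewer added sites there.

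For the patterns that follow, the tests of copy number and of estradiol were chosen only after the result was at least partly seen, and the other tests before. For the broad peaks, the tables argue against estradiol treatment as the source of the crowding on chromosomes 3, 17 and 20, since without it 100% of the 67 broad vehicle peaks (94.6 to 100%) lay there, against 15.0% of narrower vehicle peaks (14.5 to 15.5%). These chromosomes were picked after the peaks were seen, and whether estradiol made single peaks broad was not tested. A candidate explanation is copy-number gain raising local read density, because MCF-7 is known to carry amplified segments on 17q and 20q. It stays open, because its test restates the pattern that prompted it: 88.1% of broad vehicle peaks (78.2 to 93.8%) lay in the 10 fullest 1 Mb windows of the broad E2 peaks, which dense true binding there would give too.

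For the 60 E2-only peaks among the 1000 highest E2 peaks, differently drawn peak edges are argued against, since 3.33% of them (0.919 to 11.4%) had a vehicle peak within 1 kb of an edge. Copy-number gain on chromosomes 3, 17 and 20 is argued against as the source of most of them, since only 10% of them (4.66 to 20.1%) lay there. A majority there was unlikely from the start, as only 18.6% of the shared high peaks lay there. Copy number was not measured, and gain on other chromosomes was not tested. As the source of the 6 on chromosomes 3, 17 and 20, copy-number gain would need a larger share there than among the shared high peaks. The share was lower than theirs (18.6%, 16.3 to 21.2%), but the intervals overlap, so this stays open. The depth or threshold of the vehicle library stays open, since 51 of the 1000 peaks met a vehicle peak scoring under 100, close to the 60 that met none, so absence may be the low tail of a continuous range. Estradiol treatment stays open too and cannot be told apart from any other difference between the libraries, because each condition has 1 library.

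The share of E2 peaks also listed with vehicle differed between chromosomes by 11.1 percentage points. Score composition is argued against as the cause of this range, since weighting every chromosome to the same score deciles left 113% of it (bootstrap interval 88.1 to 133%), with chromosome 19 at 37.2% and chromosome 12 at 49.8%. The range is set by the chromosomes at its ends. Score composition is therefore not excluded for differences among the other chromosomes. Chance placement of the shared peaks stays open. A range as large came from 235 of 1000 rotations of the shared calls along the genome. Each rotation, however, keeps stretches with few shared peaks, such as that of chromosome 19, as whole blocks. It therefore cannot show whether those stretches themselves arose by chance. GC content and gene density were not tested, as no hg18 sequence or annotation was used.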
